A study of Danio rerio with 6 samples.

How the data were processed

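Small RNA libraries were made from zebrafish primordial germ cells with a microscale small RNA method, per the labels' protocols, at 6, 11 and 24 hpf with 2 libraries per stage. Bowtie 1.0.0-5 and the genome build danRer11 are named in the submitters' processing notes. The rule for counting reads that match several microRNAs and the microRNA annotation are not given in the sources used here. The deposited table gives, for each of 134 mature microRNAs, its sequence, its count of reads in each library, and an RPM value. The counts are whole numbers that the authors did not normalise, as far as the file shows. The RPM values deposited by the authors equal the count times 1 constant per library, which implies library totals of 9019179 to 21230244 reads. Which reads those totals count is not given in the sources used here. No column came from another series. Identical sequences were listed under 2 pairs of names, let-7c-3p with let-7d-3p and miR-126a-5p with miR-126b-5p, whose counts cannot be separated.

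The counts were tested with edgeR 4.0.16 in R 4.3.3. microRNAs were kept by filterByExpr with a minimum count of 10, which left 69 of 134, and 65 were not tested. Libraries were scaled by TMM, with factors from 0.55 to 1.68, and the quasi-likelihood fit used all 6 libraries with stage as the only term. An adjusted p under 0.05 (Benjamini-Hochberg over the 69) was called a change. The standard error of a log2 difference was taken as its size divided by the square root of F. Before the data were examined, the test, samples, 20 microRNA lists, named microRNAs and a first set of alternatives had been fixed. The robust option of the fit had not been fixed. It was tried first, giving 4, 0 and 4 changes between 6 and 11, 11 and 24, and 6 and 24 hpf, and the tool's default (4, 0 and 12) was then taken as the main form. The choice of the default was therefore made after those counts had been seen.

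The named microRNAs were, per comparison, up to 12 rises and 12 falls past the threshold whose libraries did not overlap. Where fewer than 5 passed, the 5 largest differences without overlap were added and named as not passing. Also named were the 10 most abundant microRNAs per stage, measured miR-430 members, and 2 to 4 members per list with the lowest p. Lists with 3 or more tested members, 10 of the 20, were tested by camera in limma 3.58.1 with a preset correlation of 0.01, by camera with an estimated correlation, and by fry. A fold against a stage with 0 reads was computed as a lower bound against 3 reads over the stage, which covers counting error only. With 1 to 3 reads, a ratio was given with an exact 95% counting interval. Shares of reads were compared by exact two-sided permutation tests in SciPy 1.17.1.

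Scripts were tested on simulated data for the comparison of 24 with 6 hpf, in 50 runs with 20 of the 69 microRNAs changed. With as many rises as falls, 14.0% of 4-fold and 55.8% of 16-fold changes were called, and 4.17% of calls were false. With every change upwards, the form run first, the shares were 10.9% and 50.4%, with 4.59% false. In that form camera gave p under 0.05 for 66% of unchanged lists and the estimated correlation for 0%. The balanced form was added after this result, and there both gave 0%, for lists of 8 members in place of 20. Most true 4-fold changes would thus be missed with 2 libraries per stage. No simulated change was placed in the miR-430 family. The shares of false calls therefore do not cover errors from a shift in that family between stages.

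Alternatives covered RLE scaling, library size only, leaving out the miR-430 family, DESeq2 1.42.0, no filter, a stricter filter (mean of 100 reads in at least 1 stage), the replicate number as a term, each library left out, and fits of only the 2 stages compared. Where a library was left out, the remaining one of its stage was assumed to vary like the others. Leaving out libraries and the fits of 2 stages were first run with the filter recomputed and then with those of the 69 microRNAs that had reads in the libraries left, a change made after the first counts had been seen, and both forms are given. That was all 69 where 1 library was left out, and 65, 68 and 69 in the fits of 6 and 11, 11 and 24, and 6 and 24 hpf. Leaving out the miR-430 family came before the filter, which then kept 58. Chosen after seeing the data were also the authors' library totals, the robust and newer quasi-likelihood fits, a filter on reads in both libraries of a stage, and thinning. The reference tables were not used, since their assembly differs from danRer11 and no genome was given, and no coordinates are reported. Figures were drawn with matplotlib 3.10.9.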

Results

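Mature microRNAs were counted in primordial germ cells of the zebrafish AB strain, the embryonic cells that give rise to eggs and sperm. The cells had been picked by their green fluorescence at 3 developmental stages. These were the shield stage at 6 hours post fertilization (hpf), the 3-somite stage at 11 hpf and the prim-5 stage at 24 hpf. Each stage had 2 libraries, and the question was how the microRNA content of these cells differed between stages. The table listed 134 mature microRNAs. microRNA reads numbered 35718 and 63849 in the 6 hpf libraries, 45309 and 48199 in the 11 hpf libraries, and 66864 and 78973 in the 24 hpf libraries. They made up between 0.317% and 0.571% of the library totals that the authors' RPM values imply. A count of 0 in a library allowed a level of up to 38.0 to 84.0 RPM of microRNA reads, depending on the library and taking 3 reads as the floor. Reads amplified by PCR are not independent molecules, so the floors, 'at least' folds and intervals given here cover counting error only. In 50 cases a microRNA had at least 10 reads in 1 library of a stage and 0 in the other. A count of 0 can thus exceed counting error, and an 'at least' fold is not a firm lower bound. The labels do not say that the libraries of a stage came from separate collections of embryos, so p-values measure the spread between these libraries, which may be technical.

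The miR-430 family, which clears maternal mRNAs in the early zebrafish embryo, supplied most microRNA reads at every stage. Its share was 89.1% ± 2.11 (SD, n = 2) at 6 hpf, 82.4% ± 3.16 (SD, n = 2) at 11 hpf and 69.6% ± 5.82 (SD, n = 2) at 24 hpf. The libraries of the 3 stages did not overlap in this share, and the exact two-sided permutation test gave p = 0.333 for each pair of stages, the smallest p that 2 against 2 libraries allow. The most abundant microRNA was miR-430a-3p (TAAGTGCTATTTGTTGGGGTAG), with 48.6% ± 0.45 (SD, n = 2) of reads at 6 hpf, 51.5% ± 2.96 at 11 hpf and 47.2% ± 2.84 at 24 hpf. miR-430b-3p came next, with 22.2% ± 1.20 (SD, n = 2), 27.6% ± 0.36 and 18.9% ± 2.73. The sequences of miR-430a-3p and miR-430i-3p differ by an edit distance of 1, so the division of reads between these names is uncertain. miR-430i-3p had 0 or 1 reads in each library. With the 3p arms alone, the family's share was 71.1% ± 1.67 (SD, n = 2), 79.7% ± 2.73 and 66.8% ± 5.77 at the 3 stages. The 11 hpf share was thus the highest of the 3. In this 3p share the 6 and 24 hpf libraries overlapped, with 69.9% and 72.3% against 70.9% and 62.7%.

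Outside the miR-430 family, miR-92a-3p of the miR-17-92 cluster and the broadly expressed miR-26a-5p were the most abundant. miR-92a-3p held 2.61% ± 0.87 (SD, n = 2), 4.75% ± 0.14 and 6.39% ± 0.82 of microRNA reads at 6, 11 and 24 hpf. miR-26a-5p held 1.57% ± 0.25, 4.31% ± 0.68 and 12.6% ± 3.31. The 10 most abundant microRNAs at 6 hpf also included let-7f, miR-146a, miR-92a-5p and let-7c-5p, each at 0.47% to 0.68%. miR-146a differed widely between the 6 hpf libraries, with 105 and 662 reads. At 24 hpf miR-100-5p, let-7a, miR-21, miR-430c-3p and miR-92b-3p were among the 10 most abundant, at 1.03%, 0.73%, 0.72%, 0.70% and 0.67%. Detected microRNAs, those with at least 1 read, numbered 72 ± 1.41 (SD, n = 2) at 6 hpf, 81 ± 1.41 at 11 hpf and 97.5 ± 3.54 at 24 hpf. Thinned to 35718 reads per library, the numbers were 67.9 ± 4.36 (SD, n = 2), 77.5 ± 1.60 and 89.9 ± 8.55. Thinning was over all microRNA reads, so it did not equalise the reads outside the miR-430 family, whose share grew with stage. The rise in detected microRNAs cannot be told apart from that shift.

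**Figure D1:**
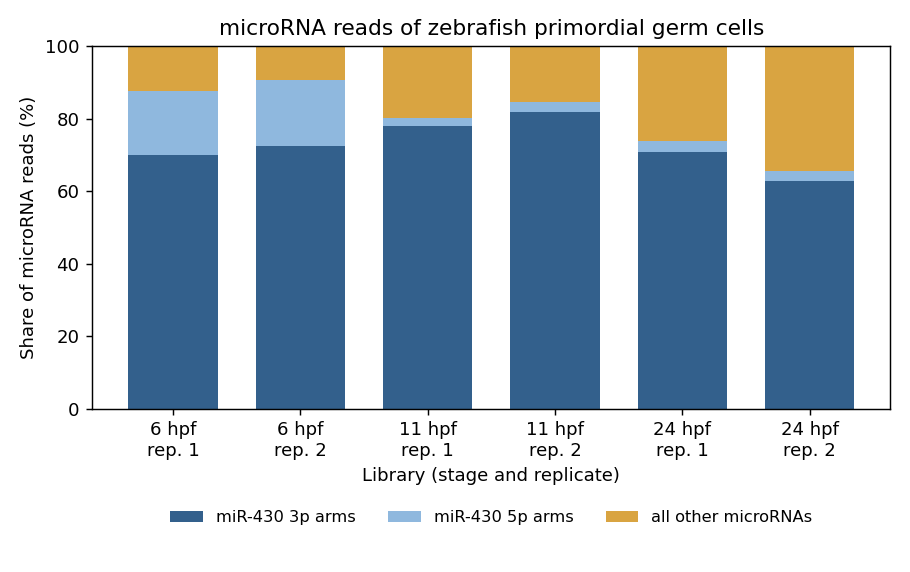
Share of microRNA reads (%) in each of the 6 libraries, as stacked bars for the 3p arms of the miR-430 family, its 5p arms and all other microRNAs. The family's total is 87.6% and 90.6% in the 6 hpf libraries and 73.7% and 65.4% in the 24 hpf libraries, and the 5p part is visibly larger at 6 hpf.

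Between 6 and 11 hpf, miR-92b-3p (TATTGCACTCGTCCCGGCCTCC), a member of the miR-92 seed family, rose from 1 and 2 reads in the 6 hpf libraries to 123 and 93 in the 11 hpf libraries. The ratio of normalised reads was 46.8 (95% counting interval 15.8 to 229; edgeR adjusted p = 0.0055). Both 11 hpf libraries lay above both 6 hpf libraries, which the naming rule required, and 27 of 69 tested microRNAs had no overlap in this comparison. Of 3 tested 5p arms of miR-430, 2 fell. miR-430i-5p (ACCCTCACAAAAGCACTGACT) fell by 3.44 on the log2 scale (SE 0.37, edgeR adjusted p = 0.017), a 10.9-fold lower level. miR-430a-5p (ACCCTCACAAAGGCACTGACT) fell by 3.35 (SE 0.38, edgeR adjusted p = 0.017). With the authors' library totals for scaling, the same arms stood at -2.75 and -2.69 and did not pass (edgeR adjusted p = 0.067 and 0.062). miR-430b-5p, with 0 and 31 reads at 6 hpf and 0 and 15 at 11 hpf, did not pass (-1.48, SE 3.06).

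miR-430i-5p made up 16.4% ± 0.12 (SD, n = 2) of microRNA reads at 6 hpf and 2.41% ± 0.38 at 11 hpf. The sequences of miR-430i-5p and miR-430a-5p differ by an edit distance of 1, so the division of reads between these names is uncertain. Summed over the family, the 5p share of miR-430 reads was 20.2% ± 0.02 (SD, n = 2) at 6 hpf and 3.24% ± 0.39 at 11 hpf. The 3p arms did not pass the test. miR-430a-3p differed by -0.60 (SE 0.31, edgeR adjusted p = 0.524), with a value of 0.09 when only library size was used for scaling. Relative to the median of the tested microRNAs, these values were -0.52 and -0.35. miR-724 fell from 27 reads to 0, at least 13.9-fold lower (edgeR adjusted p = 0.041), a call that held in 4 of 23 alternative settings. The calls on miR-430i-5p and miR-430a-5p held in 16 and 12 of 24, and that on miR-92b-3p in 23 of 25. Settings in which a microRNA was not tested are not counted in these totals. Fits with a library left out, or of only the stages compared, are counted in both of their forms.

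In all, 4 of 69 tested microRNAs changed between 6 and 11 hpf by edgeR's quasi-likelihood test, 1 upwards and 3 downwards, and 9 had an unadjusted p under 0.05. Not passing were miR-92a-2-5p, at least 49.3-fold lower at 11 hpf, and miR-146b, a microRNA of the NF-kB feedback loop, at least 9.31-fold higher. Also not passing was miR-92a-5p with a log2 difference of -4.96 (SE 1.41), from 273 and 304 reads to 28 and 1. miR-2189 and miR-183-5p, neither passing, each rested on a single 11 hpf library. miR-2189 had no reads at 6 hpf and 1 and 32 at 11 hpf, and miR-183-5p had 1 and 0 reads at 6 hpf and 40 and 3 at 11 hpf. miR-26a-5p, at 0.79 (SE 0.14, edgeR adjusted p = 0.053), did not pass either. The count was 0 without 6 hpf replicate 2, 2 without 11 hpf replicate 1 and 2 without 24 hpf replicate 1. It was also 0 when only the 2 stages compared entered the fit, and 7 with DESeq2. With library size only, 2 rose and 2 fell, and with RLE size factors 2 rose and 3 fell.

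None of the 10 microRNA lists with at least 3 tested members passed camera in this comparison, and 1 had an unadjusted p under 0.05. In the miR-430 family 2 of 6 tested members fell and 4 did not pass, and 2 fell when adjusted over the list alone. Its camera adjusted p was 0.220 (adjusted p = 0.926 with an estimated correlation), and without 6 hpf replicate 1 it passed (adjusted p = 0.0125, adjusted p = 0.973 with an estimated correlation). In the miR-17-92 and paralogue list 1 of 8 tested members rose, miR-92b-3p, and adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.760). miR-20a-5p of that list differed by 1.37 (SE 0.67) and miR-25-3p by 0.79 (SE 0.52), neither passing. Of the 6 tested let-7 members none passed, with let-7f at -0.30 (SE 0.28) and let-7i at -0.29 (SE 0.25). miR-26a-5p rose when adjusted over the list alone, that of broadly expressed microRNAs, and no member of the other 6 lists passed either way.

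Between 11 and 24 hpf no microRNA passed the threshold of edgeR's quasi-likelihood test, while 14 of 69 had an unadjusted p under 0.05 and DESeq2 called 3. Reads of miR-182-5p, of the miR-183 cluster that marks sensory organs, numbered 0 at 11 hpf and 131 at 24 hpf, at least 20-fold higher. miR-10c-5p, of a Hox-cluster family, had 0 and 186 reads, at least 28.3-fold higher. miR-724, miR-16c-5p and miR-456 were at least 14.8-fold, 13.6-fold and 15.1-fold higher at 24 hpf, with miR-456 at 12 and 87 reads in the 24 hpf libraries. None of these 5 passed. For each, both 24 hpf libraries lay above both 11 hpf libraries, but the rule that named them required this. Of the 69 tested microRNAs, 32 had no overlap in either direction in this comparison. By chance 33.3% would have none if no values were tied, and microRNAs without reads at both stages cannot qualify.

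The smallest edgeR adjusted p in this comparison was 0.057, shared by miR-26a-5p, miR-724 and miR-210-5p. miR-26a-5p differed by 1.08 (SE 0.14), let-7i by -1.24 (SE 0.25), let-7f by -1.06 (SE 0.28) and miR-99 by -1.14 (SE 0.21), none passing. With RLE size factors in place of TMM, 8 microRNAs passed, 4 higher and 4 lower. Among microRNAs with reads in both libraries of at least 1 stage, a filter chosen after seeing the data, 12 passed. No list passed camera, with 1 of 10 at an unadjusted p under 0.05. Adjusted over the list alone, 3 of 6 tested let-7 members fell, while 0 of them passed over all microRNAs (camera adjusted p = 0.181, adjusted p = 0.879 with an estimated correlation). Also adjusted over the list alone, 1 of 3 tested members rose in the Hox-cluster list and 1 of 4 in the miR-15/16 list. The same held for 1 of 5 in the broadly expressed list, and 1 of 4 fell in the family of miR-99 and miR-100. No member passed in the other 5 lists.

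Between 6 and 24 hpf, miR-92b-3p rose from 3 to 983 reads, a ratio of 97.3 (95% counting interval 33.2 to 472; edgeR adjusted p = 0.0030). miR-26a-5p (TTCAAGTAATCCAGGATAGGCT) rose by 1.87 on the log2 scale (SE 0.14, edgeR adjusted p = 0.0047), 3.65-fold. miR-430i-5p fell by 3.86 (SE 0.38, edgeR adjusted p = 0.0094) and miR-430a-5p fell by 3.65 (SE 0.39, edgeR adjusted p = 0.0097). miR-92a-5p fell by 8.82 (SE 1.72, edgeR adjusted p = 0.045), from 577 reads to 4.

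Several microRNAs near the detection floor at 6 hpf rose. miR-140-3p, a cartilage microRNA, rose by 4.01 (SE 0.82), from 4 reads to 230. Reads of miR-146b, miR-182-5p and miR-210-5p numbered 0 at 6 hpf and 209, 131 and 68 at 24 hpf. These were at least 20.7-fold, 13.0-fold and 6.73-fold higher, and their edgeR adjusted p-values lay between 0.039 and 0.045. let-7i fell by 1.53 (SE 0.26), let-7f fell by 1.36 (SE 0.28) and miR-99 fell by 1.22 (SE 0.21), with edgeR adjusted p-values of 0.039, 0.045 and 0.040. These 3 calls were lost when only library size was used for scaling, where the values were -0.39, -0.24 and -0.09, and with the authors' library totals, where miR-99 stood at 0.01. The sequence of let-7f is near-identical to that of let-7a, and miR-99 to miR-100-5p, so the division of reads between these names is uncertain.

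The choice of scaling moved the whole distribution. The median log2 difference of the 69 tested microRNAs was -0.36 with TMM, 0.18 with RLE, 0.74 with library size only and 1.05 with the authors' library totals. Relative to that median, let-7i stood at -1.17 with TMM and -1.36 with the authors' totals, miR-99 at -0.86 and -1.04, and miR-26a-5p at 2.23 and 2.05. Relative to it, miR-430i-5p stood at -3.49 and -3.66 and miR-430a-5p at -3.29 and -3.49. miR-430a-3p did not pass, and stood relative to the median at -0.79 with TMM, -0.78 with RLE and -0.96 with the authors' totals, while its value before the median was taken off went from -1.15 to 0.09.

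In all, 12 of 69 tested microRNAs changed between 6 and 24 hpf, 6 upwards and 6 downwards, and 24 had an unadjusted p under 0.05. The libraries of these stages did not overlap for 47 of the 69. With library size only, 16 changed, 12 upwards and 4 downwards. With the authors' library totals 18 changed, 14 upwards and 4 downwards, and with RLE 14 changed, 6 upwards and 8 downwards. With the miR-430 family left out and the filter applied anew, 11 of 58 tested changed, 9 upwards and 2 downwards, and DESeq2 called 16, 9 upwards and 7 downwards. The count depended on single libraries: it was 4 without 6 hpf replicate 1, 0 without 6 hpf replicate 2, 28 without 11 hpf replicate 1, 24 without 11 hpf replicate 2, 2 without 24 hpf replicate 1 and 1 without 24 hpf replicate 2. It was also 28 when only the 2 stages compared entered the fit. The call on miR-92b-3p held in 24 of 25 alternative settings, that on miR-26a-5p in 22 of 25, and those on miR-430i-5p and miR-430a-5p in 19 of 24 each. miR-92a-5p was called in 17 of 25, miR-140-3p in 14 of 25, miR-146b in 13 of 25, miR-182-5p in 11 of 24 and miR-210-5p in 9 of 24. miR-99 was called in 5 of 25, and let-7f and let-7i in 8 of 25 each. Settings in which a microRNA was not tested are again not counted, such as the stricter filter for miR-182-5p and miR-210-5p.

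**Figure D2:**
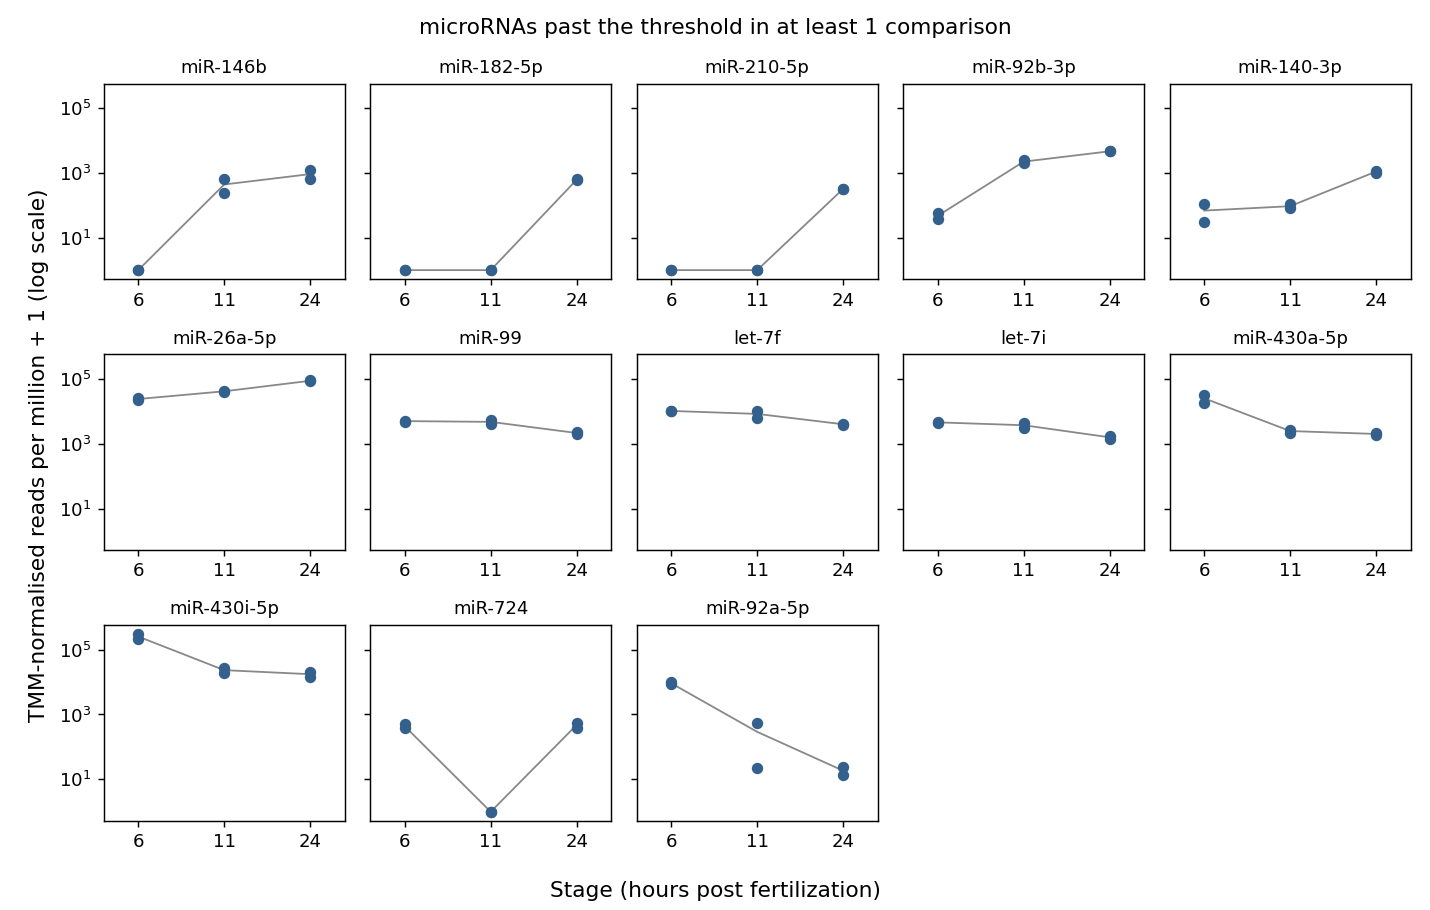
TMM-normalised RPM plus 1, on a log axis, against stage (hpf) for the 13 microRNAs past the threshold in at least 1 comparison. Points are the 2 libraries of a stage and lines join their means, with miR-92b-3p at 3 reads in all at 6 hpf and 983 at 24 hpf.

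No list passed camera between 6 and 24 hpf, and 1 of 10 had an unadjusted p under 0.05. In the miR-430 family 2 of 6 tested members fell, and adjusted over the list alone 4 fell (camera adjusted p = 0.0610, adjusted p = 0.949 with an estimated correlation). Without 6 hpf replicate 1 the family passed camera (adjusted p = 0.0134, adjusted p = 0.959 with an estimated correlation). In the let-7 family, which promotes differentiation in many animals, 2 of 6 tested members fell, and adjusted over the list alone 4 fell (camera adjusted p = 0.327). Its member let-7g had 0 reads at 6 hpf and 633 at 24 hpf, at least 62.6-fold higher, and did not pass. For this reason the mean difference of the list was above 0, while its median and its camera direction were below. In the miR-17-92 and paralogue list 1 of 8 tested members rose, miR-92b-3p, and 1 fell, miR-92a-5p, and adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.945). The mean of this list was below 0, and its median and camera direction above. miR-99 was the 1 of 4 tested members of its family that fell, also when adjusted over the list alone, while miR-100-5p differed by 0.32 (SE 0.32). The sequences of miR-99 and miR-100-5p are near-identical, as are those of let-7a, let-7f and let-7g. The division of reads between these names is therefore uncertain. In the broadly expressed list 1 of 5 rose, miR-26a-5p, also when adjusted over the list alone.

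In the test of fry for change in either direction, 3, 5 and 8 of the 10 lists passed between 6 and 11, 11 and 24, and 6 and 24 hpf. In its test of a common direction 0 passed. Fry compares a list with no other microRNAs, so 1 strongly changed member can make it pass. Between 6 and 24 hpf the broadly expressed list passed with miR-26a-5p as its only member past the threshold. The Hox-cluster, miR-15/16, miR-30 and miR-181 lists had no member past the threshold over all microRNAs between 6 and 24 hpf, and 1 of 4 in the miR-15/16 list rose when adjusted over the list alone. Their camera adjusted p-values were 0.691, 0.945, 0.945 and 0.945. miR-10c-5p was at least 18.4-fold higher at 24 hpf, miR-16c-5p at least 8.81-fold and miR-16b at least 18.3-fold. miR-10b-5p differed by 1.05 (SE 0.47), miR-30d by 0.43 (SE 0.48), miR-30e-3p by -1.05 (SE 0.92) and miR-181a-5p by -0.37 (SE 0.49). In the mesenchyme list miR-143, a smooth muscle microRNA, differed by -1.13 (SE 0.34).

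microRNAs typical of other cell types were measured in the same libraries. The purity of the picked cells was not measured here. Reads from other cells therefore cannot be told apart from expression in the germ cells. This limit also holds for the rises of miR-182-5p and miR-140-3p. The sensory organ list (miR-183-5p, miR-182-5p and miR-96-5p) took 0.00280% and 0.00313% of microRNA reads in the 6 hpf libraries, 0.0949% and 0.0145% at 11 hpf, and 0.262% and 0.409% at 24 hpf. Its member miR-182-5p is among those that rose between 6 and 24 hpf, and miR-183-5p did not pass. The mesenchyme and cartilage list took 0.690% ± 0.145 (SD, n = 2), 0.875% ± 0.389 and 0.901% ± 0.136, with 1 of 6 tested members, miR-140-3p, rising between 6 and 24 hpf. Only that member lay above 0, and the list had a median log2 difference of -0.84 and a downward camera direction (camera adjusted p = 0.945). All shares here are of all microRNA reads, of which the miR-430 family took 89.1% at 6 hpf and 69.6% at 24 hpf. A rising share can thus go with falling normalised levels. The muscle list took 0.0218% ± 0.0087 (SD, n = 2), 0.0408% ± 0.0078 and 0.107% ± 0.026 at 6, 11 and 24 hpf. The neural list took 0.0867% ± 0.052, 0.10% ± 0.024 and 0.146% ± 0.042. Its tested members lay below 0 at 24 against 6 hpf, with miR-7a at -1.12 (SE 0.62) and miR-128-3-5p without reads at 24 hpf. The epithelial list took 0.0714% ± 0.030, 0.0215% ± 0.0070 and 0.0256% ± 0.0040. In several lists with few reads, single libraries decided the level. In the epithelial list, miR-200b-3p had 3 and 56 reads in the 6 hpf libraries. In the neural list, miR-124-3p had 32 and 0 reads and miR-9-4-3p 0 and 42 in the 24 hpf libraries. The blood and endothelial list took 0.0476% and 0.0423% in the 6 hpf libraries, 0.0883% and 0.0145% at 11 hpf, and 0.0224% and 0.0760% at 24 hpf. The endoderm list had 15 and 2 reads at 6 hpf, 2 and 19 at 11 hpf, and 0 and 50 at 24 hpf. miR-202, a germline microRNA, is not analysed here.

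Across all 3 stages, the quasi-likelihood F test of edgeR called 5 of 69 microRNAs, which were miR-92b-3p, miR-26a-5p, miR-430i-5p, miR-430a-5p and miR-210-5p, and 20 had an unadjusted p under 0.05. This count was 3 without 6 hpf replicate 1, 0 without 6 hpf replicate 2, 16 without 11 hpf replicate 1, 17 without 11 hpf replicate 2, 0 without 24 hpf replicate 1 and 2 without 24 hpf replicate 2. Across the 69 tested microRNAs, which are not independent replicates, log2 levels correlated between libraries of a stage with Pearson's r of 0.788 to 0.905, and between libraries of different stages with 0.547 to 0.806. The 11 hpf libraries were the least alike of the 3 pairs of replicates, at 0.788. Over the 33 microRNAs of a stricter filter, their correlation was 0.817. There 11 hpf replicate 1 correlated at 0.848 and 0.859 with the 6 hpf libraries and at 0.739 and 0.802 with the 24 hpf libraries. For 11 hpf replicate 2 the values were 0.726 and 0.754 with the 6 hpf libraries and 0.907 and 0.886 with the 24 hpf libraries. Over the 69 microRNAs this parting was not seen, with values of 0.786 and 0.782 against 0.738 and 0.806 for replicate 1, and 0.746 and 0.790 against 0.778 and 0.775 for replicate 2.

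**Figure D3:**
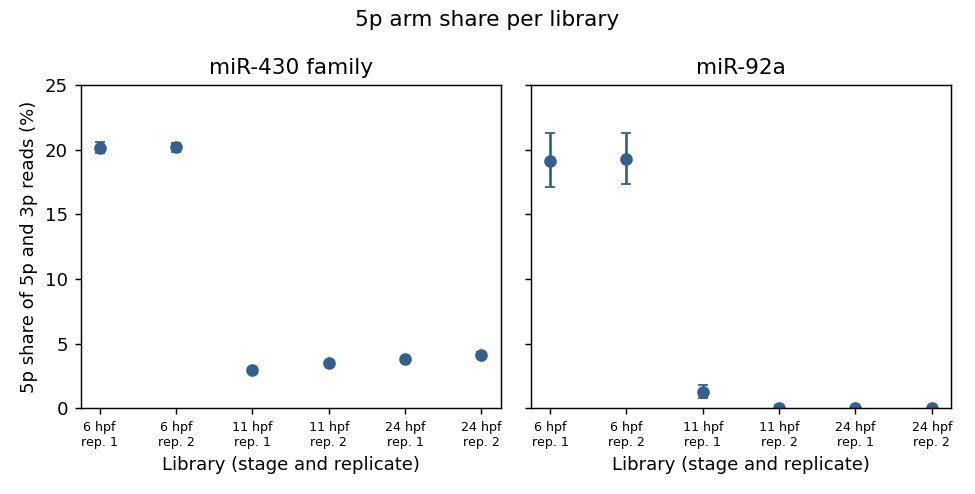
Share of 5p reads among 5p and 3p reads (%) of the miR-430 family and of miR-92a in each library, with exact 95% binomial intervals. The 6 hpf libraries stand at 20.2% and 20.2% for miR-430 and at 19.2% and 19.3% for miR-92a, and the later libraries lie below 5%.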

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

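Chosen after seeing the data were the settings with the authors' library totals, the robust and newer quasi-likelihood fits, reads in both libraries of a stage and thinning. So was keeping those of the 69 tested microRNAs that had reads when libraries were left out or only 2 stages fitted, since the filter had first been recomputed there. Counts of changes are given against 4 (11 against 6 hpf), 0 (24 against 11 hpf), 12 (24 against 6 hpf) and 5 (across stages) as reported, and the cause of each shift was not tested. RLE gave 8 at 24 against 11 hpf and 15 across stages. Library size only gave 16 across stages. Without the miR-430 family and with the filter applied anew, 1 changed at 11 against 6 hpf and 11 across stages. DESeq2 gave 7, 3 and 11 for 11 against 6 hpf, 24 against 11 hpf and across stages. No filter gave 5 at 24 against 6 hpf, and the stricter filter 1 at 24 against 11 hpf. With the authors' totals the counts were 1, 3 and 2 for 11 against 6 hpf, 24 against 11 hpf and across stages, and miR-99 reversed at 24 against 6 hpf, to 0.010 (-1.04 relative to the median). The robust fit gave 4 at 24 against 6 hpf. The newer fit gave 2 at 24 against 11 hpf and 9 across stages. With reads required in both libraries of a stage, the counts were 12, 19 and 18 at 24 against 11 hpf, 24 against 6 hpf and across stages. Fits of only the 2 stages compared gave 0 at 11 against 6 hpf and 28 at 24 against 6 hpf, and with the filter recomputed 1 and 25. Leaving out 1 library at a time gave 0 to 3 at 11 against 6 hpf, 0 to 28 at 24 against 6 hpf and 0 to 17 across stages. With the filter recomputed, the counts at 24 against 6 hpf were 7 and 5 without 6 hpf replicates 1 and 2, 17 and 15 without the 11 hpf ones, and 2 and 1 without the 24 hpf ones. Leaving out 1 library gave 0 or 1 list passing camera at 11 against 6 hpf and likewise at 24 against 6 hpf. No pairing of libraries by replicate number was seen, since deviations of same-numbered libraries correlated at 0.14, 0.06 and -0.24 across the tested microRNAs. With 2 libraries per stage these values cannot exclude a pairing. With the replicate block, the counts were 4 at 24 against 6 hpf and 3 across stages. The miR-430 share at 6 hpf was 71.1% with the 3p arm only. At a floor of 10 reads, 43, 51.5 and 74 microRNAs were detected at 6, 11 and 24 hpf, and 67.9, 77.5 and 89.9 after thinning. The alternative of another added constant was not run, since the values are counts.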

Other observations

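All tests in this part were chosen only after the results had been seen, and further tests, of library handling by stage, of scaling for miR-92a and of reads found in 1 library of a stage, were dropped. Between 6 and 11 hpf the 5p arm of miR-92a fell against its 3p arm, as did the miR-430 5p arms. Its share of miR-92a reads was 19.2% ± 0.08 (SD, n = 2) at 6 hpf, 0.65% ± 0.86 at 11 hpf and 0.040% ± 0.020 at 24 hpf, and the 11 hpf libraries held 28 and 1 reads of it. From 11 to 24 hpf the 5p share of miR-430 reads went from 3.24% ± 0.39 to 3.97% ± 0.25 and did not fall further. miR-92a-2-5p, from another miR-92a locus, had 31 and 65 reads at 6 hpf and 0 in the 4 later libraries. miR-15b-3p had 99 and 69 reads at 6 hpf, 0 and 63 at 11 hpf and 0 in both 24 hpf libraries. let-7g had 0 reads in 3 of the 4 earlier libraries, 127 in 11 hpf replicate 2, and 336 and 297 at 24 hpf. The miR-23/24/27 list had 8 and 6 reads at 6 hpf, 8 and 5 at 11 hpf, and 67 and 12 at 24 hpf. The miR-130 list had 54 and 47 reads at 6 hpf, 1 and 11 at 11 hpf, and 2 and 38 at 24 hpf. miR-29a had 1 read in 1 library. In 50 cases a microRNA had at least 10 reads in 1 library of a stage and 0 in the other, 16 of them in 24 hpf replicate 1. Among all 97 values above 0 whose partner library had 0, 43 were of 1 to 3 reads, 4 of 4 to 9 and 50 of 10 or more.

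Summed 5p reads of the miR-430 family fell against summed 3p reads between 6 and 11 hpf. Library scaling cannot move this ratio, which fell in each of the 4 pairs of libraries, at least by a log2 difference of -2.79. Reads divided among near-identical 5p names do not account for it, since the ratio of the sums changed by -2.92. A loss of rarer arms in general stays open: over the 4 other microRNAs with at least 3 reads of both arms in both 6 hpf libraries, the rarer arm changed by -6.34 in miR-92a and by -0.44 to 0.46 in the other 3, a median of -0.20. This choice of microRNAs replaced one that also asked for 11 hpf reads and left out miR-92a, and a difference between the stages themselves, which the design names, stays open as well.

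A hypothesis was that microRNAs with the miR-92 seed (ATTGCAC) rose together. Their joint share of microRNA reads was 2.84% ± 0.86 (SD, n = 2), 5.62% ± 0.08 and 7.88% ± 0.76 at 6, 11 and 24 hpf, and of reads outside the miR-430 family, whose own share fell, 25.7% ± 2.90, 32.5% ± 6.28 and 26.1% ± 2.51. Of the 4 members only miR-92b-3p passed, at 11 against 6 hpf and at 24 against 6 hpf, where miR-92a-3p, miR-25-3p and miR-363-3p stood at 0.21, 0.68 and 1.17, and at 24 against 11 hpf none passed and 2 of 4 lay above 0 (fry adjusted p = 0.366). With an estimated correlation in camera the set did not pass at 24 against 6 hpf (p = 0.144, adjusted p = 0.499 over 5 seed sets, and adjusted p = 0.163 with the preset) or at 11 against 6 hpf (adjusted p = 0.257, and 0.0141 with the preset), while fry for a common direction, which compares the set with no other microRNAs, gave adjusted p-values of 0.0145 and 0.0379. The hypothesis was written after miR-92b-3p had been called, so these p-values partly reflect that choice, and no test of the set was run without it. The tables therefore leave the hypothesis undecided, and the rule for calling it excluded was rewritten after these values had been seen.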
